A study of Homo sapiens with 24 samples.

How the data were processed

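Inputs were 3 processed tables of 25680 genes each, for MV411 (12 libraries), MOLM13 (6) and OCI-AML3 (6), with 0 per-sample columns left out. Per the labels, spike-in RNA was added at a fixed amount per cell number before extraction, reads were paired 50 bp, and triplicates were called biological. How their cultures were separated was not described. P-values measure the spread between them. On the deposited scale of MOLM13, OCI-AML3 and line differences it was pooled over genes as if independent. Per the submitters, values were normalised with DESeq version 2 and genes placed on hg38. The sources gave no aligner, counting program or annotation, and raw reads were not analysed.

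The deposited values are called signal here, since per the labels they are normalised expression values. In every library all values (100% within a tolerance of 0.001) were whole numbers divided by 1 factor, so reads could be recovered. The MV411 factors equalled median-of-ratios factors of the genes, although the columns carry the name of the spike-in, whereas the MOLM13 and OCI-AML3 factors did not. For that reason results of MOLM13, OCI-AML3 and the differences between lines are given relative to the median shift, after division by median-of-ratios factors, beside counts on the deposited scale. Spike-in reads were not in the tables.

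Each comparison used limma on log2(value + 1) with a variance trend, for genes with a value of at least 10 in at least 3 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 12 MV411 libraries shared 1 fit, and the interaction was the combination minus AC220 minus MI-503 plus DMSO. Differences between lines were the difference of the within-line effects over genes kept in both tables. The threshold, the tests on the deposited scale, the lists and the naming rule were set before the data were examined. Giving gene values and list tests relative to the median shift was decided after the factors were seen. Named genes and passing members were still picked by the fit on the deposited scale. Genes named were 22 set in advance, up to 4 passing members of each list with the largest change, and the 8 largest changes per direction with a group mean of at least 100 and groups wholly apart. For the interaction and the line differences these were 2 members and 5 changes. For the combination against each drug only counts and lists are given.

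The 28 gene lists were HOXA cluster, HOXB cluster, MLL fusion targets outside HOX, STAT5 targets, ERK pathway output, MYC and ribosome biogenesis, monocyte-macrophage differentiation, granulocyte differentiation, myeloid progenitor, DNA replication, mitosis, cholesterol synthesis, lysosome, ATF4 stress response, p53 targets, BCL2 family, interferon response, MHC class II, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded, heat shock, replication-dependent histones, erythroid and megakaryocyte markers, T and NK cell markers, B cell markers, and epithelial and fibroblast markers. The mitochondrially encoded list had 0 members in the tables. Lists with at least 3 tested members went through camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation.

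A gene without reads in a group was given as a bound with 3 reads over the group, and ratios with few reads carry a 95% interval. Such intervals and bounds cover counting error only. Replicate libraries differed by more than counting error, with a chi-square per degree of freedom of 1.59 to 9.41 over 24 pairs, and no library was sequenced in duplicate. Expected overlaps assume independent calls, and 20 simulations gave the correlation that shared controls alone produce.

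A self-test simulated reads of 12905 to 15554 genes from DMSO means with the tables' factors and dispersions, changing up to 200 genes by a known fold. It held no factor error or correlation between genes, so its rates do not cover them. limma recovered 81.5%, 96% and 99.5% at 1.5, 2 and 4-fold for MI-503 in MV411, 76.5%, 88.5% and 99.5% for the interaction, 89.9%, 97.0% and 99.5% in MOLM13, 87.5%, 93.9% and 100% in OCI-AML3, and 78%, 94.0% and 99.5% for the MOLM13 and OCI-AML3 difference. False calls were 2.96% to 8.96% of calls. A changed list of 25 genes was found in each, and 0 of 40 unchanged lists had p under 0.05.

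On recovered reads edgeR and DESeq2 called 8819 and 8242 genes for MI-503 in MV411, 10866 and 10401 for AC220, 11462 and 11047 for the combination, 9913 and 9447 against MI-503, 8048 and 7425 against AC220, and 6137 and 5656 for the interaction. With the deposited factors they called 11194 and 10877 in MOLM13, 1612 and 1923 in OCI-AML3, 3156 and 3505 for MOLM13 against OCI-AML3, 2462 and 2608 for MV411 against OCI-AML3, and 9933 and 9720 for MV411 against MOLM13. Other alternatives were median-ratio scaling, equal totals, TMM factors, pseudocounts of 0.5 and 8, a minimum value of 50, no filter, no trend, only the 6 libraries compared, a replicate block, and leaving out each library. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9, and gene positions came from a GENCODE annotation.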

Results

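The series measured RNA in 3 established human acute myeloid leukaemia lines after drug treatment, in 24 libraries forming 8 groups of 3. MV411 and MOLM13 each carry an MLL (KMT2A) fusion and an internal tandem duplication of the receptor tyrosine kinase gene FLT3. OCI-AML3 carries mutant NPM1 and no MLL fusion. MI-503 blocks the contact between menin, the product of MEN1, and MLL proteins, and AC220 (quizartinib) blocks the FLT3 kinase. MV411 received DMSO, 2.5 µM MI-503 for 3 days, 3 nM AC220 for 24 h, or the pair of drugs together. MOLM13 and OCI-AML3 received DMSO or 2.5 µM MI-503 for 4 days. Reads assigned to genes per library were 26554728, 25166887 and 26411886 in MV411 with DMSO, 25245088, 26175174 and 26137469 with MI-503, 26074571, 25280544 and 26596469 with AC220, and 23168887, 25454953 and 24917528 with the combination. MOLM13 had 27240357, 25824579 and 25299839 with DMSO and 25533336, 23281330 and 25913968 with MI-503. OCI-AML3 was sequenced more deeply, with 65458071, 72994481 and 60855497 for DMSO and 44364964, 56174189 and 61848977 for MI-503.

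The MI-503 comparison in MV411 asked which genes need menin in an MLL-fusion line, and the AC220 comparison asked which need FLT3 signalling. The combination was set against DMSO and against each drug, and an interaction test asked where the combined effect left the sum of the single effects. MOLM13 served as a second MLL-fusion line and OCI-AML3 as a line without the fusion, and differences between lines were tested directly. Gene values are log2 fold changes ± standard error with n = 3 libraries per group, and adjusted p-values come from limma with Benjamini-Hochberg adjustment unless camera, its gene-list test, is named. In MOLM13, OCI-AML3 and the differences between lines, values are relative to the median shift of all genes, which is given once for each comparison. Counts of list members adjusted over the list alone equalled those adjusted over all genes unless given. Camera used a preset correlation between genes, and where a call was lost with an estimated correlation that p-value follows.

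MI-503 lowered the MLL programme in MV411. MEIS1, a cofactor gene of HOX proteins and a direct target of MLL fusions (hg38 chromosome 2, 66433452 to 66573869), fell to 0.202 of its DMSO level (-2.31 ± 0.0576, adjusted p = 1.68e-19, n = 3 per group). MEF2C, a transcription factor of the same programme (hg38 chromosome 5, 88717117 to 88904257), changed by -2.81 ± 0.0575, adjusted p = 3.84e-21, and PBX3, which binds DNA with MEIS1 (hg38 chromosome 9, 125747345 to 125967377), by -1.81 ± 0.0481, adjusted p = 5.64e-19. HOXA9 (hg38 chromosome 7, 27162435 to 27175180), the homeobox gene that cooperates with MEIS1 in leukaemia, fell (-1.88 ± 0.0596, adjusted p = 9.74e-18), as did HOXA10 (-1.53 ± 0.0565, adjusted p = 1.56e-16), whose gene model overlaps that of HOXA9 (hg38 chromosome 7, 27170591 to 27180261), so reads there are hard to assign. FLT3 itself (hg38 chromosome 13, 28003274 to 28100592) fell to 0.553 of control (-0.85 ± 0.0401, adjusted p = 1.18e-14).

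MYC, the growth regulator (hg38 chromosome 8, 127735434 to 127741434), changed by -0.88 ± 0.0419, BCL2, which blocks apoptosis, by -1.08 ± 0.0489, CDK6, a cell-cycle kinase, by -0.99 ± 0.0564, and MYB, a progenitor transcription factor, by -0.34 ± 0.0388. Among further targets CPEB2 changed by -1.60 ± 0.0565 and the cyclin gene CCND3 by -1.01 ± 0.0521, and the kinase genes PIM1 and PIM2 by -0.67 ± 0.0559 and -0.96 ± 0.0570. KMT2A, the gene broken in the fusion, changed by -0.29 ± 0.0391, while MEN1, which encodes the drug target, did not pass (-0.12 ± 0.0603, adjusted p = 0.0905). Neither did NPM1 (0.06 ± 0.0359, adjusted p = 0.185), the STAT5 feedback genes SOCS2 (-0.13 ± 0.0745, adjusted p = 0.143) and CISH (0.03 ± 0.0691, adjusted p = 0.763), or the integrin gene ITGAM (-0.19 ± 0.0824, adjusted p = 0.0562).

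With MI-503, LYZ, which encodes the monocyte enzyme lysozyme, changed by 2.55 ± 0.0434, adjusted p = 9.00e-23, CYBB, a subunit of the phagocyte oxidase, by 2.54 ± 0.129, and S100A8, a calcium-binding protein of monocytes and neutrophils, by 2.50 ± 0.10. The granule protease gene ELANE rose by 1.55 ± 0.0746 and MPO, the granule peroxidase, by 0.62 ± 0.108. Among the largest increases were SERPINB10, a serpin of myeloid cells (hg38 chromosome 18, 63897174 to 63936111), at 25.4-fold (4.67 ± 0.202) and F13A1, a coagulation factor chain made by monocytes, at 12.3-fold (3.62 ± 0.0477). The creatine transporter gene SLC6A8 changed by -4.50 ± 0.180 and the interferon-induced IFIT2 by -4.94 ± 0.214. SPP1, which encodes the matrix cytokine osteopontin, went from 1022 reads over the DMSO group to 2, a ratio of 507.7 (95% counting interval 140.2 to 4198).

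By list, of the MLL fusion targets outside HOX 0 of 20 rose and 16 fell, or 0 and 17 adjusted over the list alone, median -0.83, camera adjusted p = 7.27e-12, adjusted p = 0.0602 with an estimated correlation. In the HOXA cluster 0 of 3 rose and 2 fell, median -1.53, camera adjusted p = 0.00796, adjusted p = 0.0674 with an estimated correlation. Cholesterol synthesis genes, whose products make sterols from acetyl-CoA, fell nearly together (0 of 24 rose and 23 fell, median -1.34, camera adjusted p = 6.82e-17, adjusted p = 0.0580 with an estimated correlation). Of these, LSS, the cyclase that makes lanosterol, changed by -2.72 ± 0.0671, HMGCS1, an early enzyme of the pathway, by -2.24 ± 0.0656 and DHCR7, the last enzyme, by -2.37 ± 0.211. In the ATF4 amino-acid stress list 1 of 23 rose and 21 fell, median -0.83, camera adjusted p = 1.81e-12, with TRIB3, a pseudokinase gene induced by ATF4, at -2.71 ± 0.134 and ATF5 at -2.21 ± 0.0672. ERK output, the early targets of the RAS pathway, fell (0 of 14 rose and 13 fell, median -1.61, camera adjusted p = 1.10e-05, adjusted p = 0.0674 with an estimated correlation), with DUSP6, a phosphatase that restrains ERK (hg38 chromosome 12, 89347232 to 89353271), at -2.37 ± 0.137 and EGR1, an immediate early gene, at -2.80 ± 0.200.

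Of glycolysis genes 3 of 21 rose and 18 fell, median -0.81, camera adjusted p = 5.04e-09, adjusted p = 0.0707 with an estimated correlation. The aldolase gene ALDOC stood at -3.93 ± 0.142 and the kinase gene PGK1 at -1.4 ± 0.0391. Of MYC and ribosome biogenesis genes 2 of 28 rose and 19 fell, median -0.21, camera adjusted p = 2.24e-04, adjusted p = 0.152 with an estimated correlation. DNA replication genes fell slightly (1 of 26 rose and 19 fell, median -0.23, camera adjusted p = 0.00118, adjusted p = 0.0877 with an estimated correlation). The loading factor gene CDC6 changed by -0.99 ± 0.0969. Heat shock genes fell (0 of 11 rose and 7 fell, median -0.47, camera adjusted p = 0.00181, adjusted p = 0.229 with an estimated correlation). Of p53 targets 4 of 22 rose and 12 fell, median -0.16, camera adjusted p = 0.0394, adjusted p = 0.0877 with an estimated correlation. CDKN1A, the p53-induced kinase inhibitor, changed by -0.82 ± 0.0504. In the other direction, of lysosome genes 22 of 27 rose and 1 fell, median 0.44, camera adjusted p = 1.66e-08, with ASAH1, the acid ceramidase, at 1.68 ± 0.0462 and PSAP, a precursor of sphingolipid activators, at 1.34 ± 0.0385. For monocyte-macrophage differentiation 13 of 22 rose and 4 fell, or 13 and 5 adjusted over the list alone, median 0.50, camera adjusted p = 4.08e-04. For the myeloid progenitor list 10 of 15 rose and 1 fell, median 0.25, camera adjusted p = 0.00464, adjusted p = 0.152 with an estimated correlation. MHC class II genes, which present antigen to helper T cells, all rose (8 of 8 rose and 0 fell, median 1.61, camera adjusted p = 1.02e-06, adjusted p = 0.0674 with an estimated correlation). HLA-DQB1 rose by 2.05 ± 0.0621 and HLA-DRA by 1.77 ± 0.0824. Cytosolic ribosomal protein genes rose together (35 of 35 rose and 0 fell, median 0.44, camera adjusted p = 4.70e-16, adjusted p = 0.135 with an estimated correlation).

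Lists without a passing camera test in this comparison were STAT5 targets (3 higher and 8 lower of 15, camera adjusted p = 0.0683), interferon response (7 higher and 14 lower of 25, camera adjusted p = 0.0636), granulocyte differentiation (5 higher and 2 lower of 11, camera adjusted p = 0.0911), B cell markers (0 higher and 6 lower of 8, camera adjusted p = 0.0591), T and NK cell markers (3 higher and 0 lower of 4, camera adjusted p = 0.0941), mitosis (3 higher and 7 lower of 25, or 3 and 5 adjusted over the list alone, camera adjusted p = 0.611), oxidative phosphorylation (14 higher and 7 lower of 30, camera adjusted p = 0.413), BCL2 family (5 higher and 5 lower of 14, camera adjusted p = 0.763), replication-dependent histones (1 higher and 3 lower of 7, camera adjusted p = 0.214) and epithelial and fibroblast markers (0 higher and 1 lower of 5, camera adjusted p = 0.544). For the HOXB cluster (1 higher and 0 lower of 4, camera adjusted p = 0.763) the median was -0.02 while the mean and the test pointed up, and for erythroid and megakaryocyte markers (2 higher and 3 lower of 7, camera adjusted p = 0.674) the median was 0.11 while the mean and the test pointed down. Over all genes limma called 8734 of 14421 changed, 4299 higher and 4435 lower, of which 578 rose and 663 fell at least 2-fold. The 3 libraries of 1 group lay wholly apart from the other in 66.6% of genes, where chance alone would give 10%. Deposited factors of the MV411 libraries equalled factors computed from the genes themselves, so a change in total RNA per cell was not measured here.

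**Figure D1:**
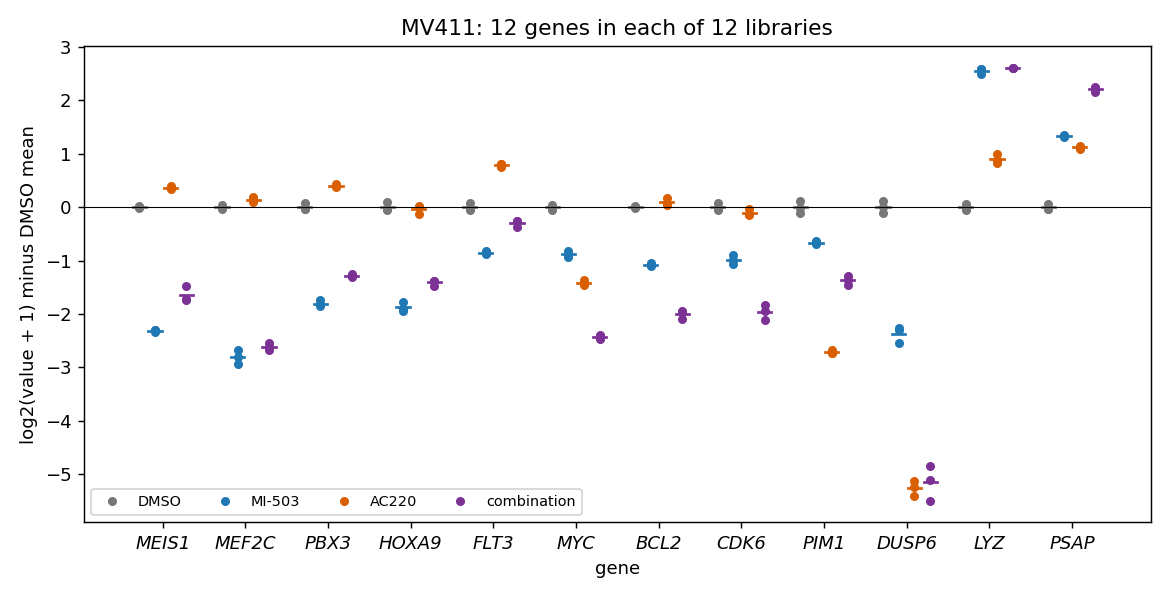
Expression of 12 genes in the 12 MV411 libraries, as log2(value + 1) minus the DMSO mean on the vertical axis and the gene on the horizontal axis. Points are single libraries, bars are group means, and colours mark DMSO, MI-503, AC220 and the combination.

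AC220 lowered the outputs of FLT3 signalling in MV411. DUSP6 fell to 0.0262 of control (-5.26 ± 0.137, adjusted p = 3.53e-20, n = 3 per group), DUSP5, a further ERK phosphatase gene, changed by -4.03 ± 0.186, adjusted p = 1.92e-15, and ETV5, a transcription factor gene induced by ERK, by -3.96 ± 0.0795, adjusted p = 3.11e-22. PIM1, a kinase gene that STAT5 induces below FLT3, fell to 0.153 of control (-2.71 ± 0.0559, adjusted p = 4.92e-22). CISH and SOCS2, feedback genes of STAT5, changed by -1.28 ± 0.0691, adjusted p = 3.85e-14 and -0.34 ± 0.0745, adjusted p = 2.64e-04, and IL2RA, a cytokine receptor gene under STAT5, by -1.52 ± 0.0746, adjusted p = 6.41e-15. MYC fell (-1.42 ± 0.0419, adjusted p = 3.58e-19).

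FLT3 rose with AC220 (0.79 ± 0.0401, adjusted p = 1.17e-14), as did MEIS1 (0.36 ± 0.0576, adjusted p = 5.66e-06) and PBX3 (0.40 ± 0.0481, adjusted p = 6.75e-08). MEF2C passed narrowly (0.14 ± 0.0575, adjusted p = 0.0311), a call lost without the variance trend and without some single libraries. HOXA9 (-0.04 ± 0.0596, adjusted p = 0.573), CDK6 (-0.10 ± 0.0564, adjusted p = 0.101), BCL2 (0.09 ± 0.0489, adjusted p = 0.0953) and MYB (0.01 ± 0.0388, adjusted p = 0.831) did not pass. KIT, the stem cell factor receptor gene, rose by 2.63 ± 0.108, BMF, a gene that promotes apoptosis, by 1.47 ± 0.0544, LYZ by 0.90 ± 0.0434 and IGF1, a growth factor gene, by 3.70 ± 0.0516. The scavenger receptor gene SCARA5 rose 55.7-fold (5.80 ± 0.193) and SIGLEC1, an adhesion receptor of macrophages, by 3.37 ± 0.139. KLHDC7B had no read with AC220 and 372 with DMSO, a decrease of at least 125-fold. AKR1C2, an aldo-keto reductase gene, had 2 reads against 569 (288.4-fold, 95% counting interval 79.47 to 2387), though reads of its close paralog AKR1C1 are hard to tell apart from its own.

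Cell-cycle genes fell as groups. Of DNA replication genes 0 of 26 rose and 26 fell, median -2.86, camera adjusted p = 8.34e-19, with MCM10, which helps start replication, at -5.53 ± 0.135 and CDC45, part of the replicative helicase, at -5.14 ± 0.101. Of mitosis genes 0 of 25 rose and 25 fell, median -2.86, camera adjusted p = 1.38e-18, adjusted p = 0.106 with an estimated correlation. MKI67, a proliferation marker, changed by -3.21 ± 0.0522 and CCNA2, a cyclin, by -3.31 ± 0.0767. Of ERK output genes 0 of 14 rose and 14 fell, median -2.89, camera adjusted p = 4.72e-06, adjusted p = 0.0641 with an estimated correlation. For STAT5 targets 2 of 15 rose and 12 fell, median -1.09, camera adjusted p = 0.00223, adjusted p = 0.139 with an estimated correlation. MYC and ribosome biogenesis genes fell nearly as 1 group (1 of 28 rose and 27 fell, median -0.93, camera adjusted p = 2.57e-11, adjusted p = 0.0641 with an estimated correlation). Cholesterol synthesis genes all fell (0 of 24 rose and 24 fell, median -2.04, camera adjusted p = 5.88e-15, adjusted p = 0.0641 with an estimated correlation). DHCR7 stood at -6.45 ± 0.211 and LSS at -3.65 ± 0.0671. Of ATF4 genes 1 of 23 rose and 22 fell, median -1.49, camera adjusted p = 9.81e-10. The serine synthesis genes PHGDH and PSAT1 stood at -4.72 ± 0.123 and -3.93 ± 0.0874 and TRIB3 at -4.70 ± 0.134.

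Of glycolysis genes 3 of 21 rose and 17 fell, median -1.06, camera adjusted p = 1.60e-06, adjusted p = 0.135 with an estimated correlation, with LDHA, the lactate dehydrogenase, at -2.09 ± 0.0425 and ALDOC at -3.44 ± 0.142. Heat shock genes all fell (0 of 11 rose and 11 fell, median -0.85, camera adjusted p = 2.05e-06, adjusted p = 0.128 with an estimated correlation), the chaperone genes HSPE1 and HSPA8 at -1.96 ± 0.0542 and -1.55 ± 0.0444. MHC class II genes all rose (8 of 8 rose and 0 fell, median 1.76, camera adjusted p = 5.72e-05, adjusted p = 0.128 with an estimated correlation). HLA-DRA rose by 1.99 ± 0.0824 and CIITA, the activator of class II transcription, by 2.04 ± 0.0690. Of lysosome genes 20 of 27 rose and 4 fell, median 0.61, camera adjusted p = 2.00e-05, adjusted p = 0.0641 with an estimated correlation. GAA, the acid glucosidase, rose by 1.28 ± 0.0654. Ribosomal protein genes rose (34 of 35 rose and 0 fell, median 0.28, camera adjusted p = 1.29e-06, adjusted p = 0.365 with an estimated correlation). For the progenitor list 11 of 15 rose and 1 fell, median 0.24, camera adjusted p = 0.0136, adjusted p = 0.259 with an estimated correlation. Histone genes rose (5 of 7 rose and 0 fell, median 1.55, camera adjusted p = 0.00505, adjusted p = 0.259 with an estimated correlation). HIST1H2BK rose by 1.77 ± 0.0686. RPPH1, also without a poly(A) tail, took 0.614 to 1.20 RPM (reads scaled to equal library totals) against 0.189 to 0.596 with DMSO, and RNA45S5 is given below. The monocyte list did not pass (12 higher and 7 lower of 22, camera adjusted p = 0.119), nor did MLL fusion targets (11 higher and 3 lower of 20, camera adjusted p = 0.164). The interferon list did not pass either (15 higher and 7 lower of 25, camera adjusted p = 0.15), its median and test pointing up and its mean down. In all, limma called 10806 of 14421 genes changed, 5432 higher and 5374 lower, 1222 and 1564 of them at least 2-fold, and groups lay apart in 77.8% of genes.

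The MI-503 and AC220 effects shared direction: 3052 genes rose and 3013 fell with each drug, against 1619 and 1653 for independent lists, and 506 and 574 went opposite ways against 1602 and 1671. The effects correlated at r = 0.570, where 20 simulations with no effect but shared DMSO libraries gave 0.503, and their covariance was 0.359 against 0.0125 simulated. The 3 DMSO libraries were too few to give each comparison at least 2 of its own, so part of the excess may come from these shared controls.

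With the combination, MYC, BCL2 and CDK6 fell further than with either drug. MYC reached 0.185 of control (-2.44 ± 0.0419, adjusted p = 2.00e-23, n = 3 per group), BCL2 0.25 (-2.0 ± 0.0489, adjusted p = 9.66e-21) and CDK6 0.256 (-1.96 ± 0.0564, adjusted p = 1.86e-19), and MYB changed by -0.75 ± 0.0388, adjusted p = 1.20e-14. MEIS1 (-1.64 ± 0.0576), MEF2C (-2.61 ± 0.0575) and HOXA9 (-1.41 ± 0.0596) stayed low, FLT3 was near its control level though it passed (-0.30 ± 0.0401, adjusted p = 3.72e-07), and PIM1 changed by -1.37 ± 0.0559. SOCS2 and CISH changed by -1.01 ± 0.0745 and -0.88 ± 0.0691 and DUSP6 by -5.15 ± 0.137. LYZ rose by 2.60 ± 0.0434, TLR8, an endosomal sensor of monocytes, by 4.48 ± 0.192, and CSF3R, the granulocyte growth factor receptor, by 1.91 ± 0.0528, whereas ITGAM (-0.13 ± 0.0824, adjusted p = 0.138) and the granulocyte list (7 higher and 3 lower of 11, camera adjusted p = 0.0774) did not pass.

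Of the monocyte-macrophage list 20 of 22 rose and 1 fell, median 1.48, camera adjusted p = 2.29e-06. The myeloid progenitor list rose as well (11 of 15 rose and 2 fell, or 11 and 3 adjusted over the list alone, median 0.42, camera adjusted p = 0.0107, adjusted p = 0.208 with an estimated correlation). For lysosome genes 24 of 27 rose and 1 fell, median 1.05, camera adjusted p = 8.69e-09. The sulfatase gene SGSH rose by 3.31 ± 0.0797, ASAH1 by 2.90 ± 0.0462 and PSAP by 2.21 ± 0.0385. Every MHC class II gene rose (8 of 8 rose and 0 fell, median 2.83, camera adjusted p = 1.76e-05, adjusted p = 0.0990 with an estimated correlation). HLA-DQA1 rose by 3.60 ± 0.173 and HLA-DRA by 2.88 ± 0.0824. Of MYC and ribosome biogenesis genes 0 of 28 rose and 28 fell, median -1.19, camera adjusted p = 5.56e-12. Of DNA replication genes 0 of 26 rose and 26 fell, median -2.86, camera adjusted p = 3.54e-15. MCM10 stood at -4.86 ± 0.135. Mitosis genes all fell (0 of 25 rose and 25 fell, median -1.83, camera adjusted p = 1.66e-12, adjusted p = 0.143 with an estimated correlation). The mitotic kinase gene CDK1 stood at -2.63 ± 0.0824. For MLL fusion targets 1 of 20 rose and 18 fell, median -0.81, camera adjusted p = 2.29e-06, adjusted p = 0.139 with an estimated correlation, and the HOXA cluster did not pass (0 higher and 2 lower of 3, camera adjusted p = 0.0848). In the ATF4 list 3 of 23 rose and 19 fell, median -1.17, camera adjusted p = 1.31e-05. PSAT1 stood at -5.33 ± 0.0874, PHGDH at -4.97 ± 0.123 and the amino-acid transporter gene SLC7A5 at -3.60 ± 0.0602. Cholesterol synthesis genes all fell (0 of 24 rose and 24 fell, median -1.81, camera adjusted p = 3.81e-12, adjusted p = 0.0804 with an estimated correlation). LSS stood at -3.42 ± 0.0671, HMGCS1 at -3.12 ± 0.0656 and SQLE, the epoxidase of the pathway, at -3.44 ± 0.0579.

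Of ERK output genes 0 of 14 rose and 12 fell, median -2.97, camera adjusted p = 1.43e-04, adjusted p = 0.0990 with an estimated correlation. For STAT5 targets 2 of 15 rose and 12 fell, median -0.88, camera adjusted p = 0.0218, adjusted p = 0.208 with an estimated correlation. Glycolysis genes fell (3 of 21 rose and 17 fell, median -1.15, camera adjusted p = 5.05e-05, adjusted p = 0.186 with an estimated correlation). LDHA stood at -2.50 ± 0.0425. Heat shock genes fell too (1 of 11 rose and 10 fell, median -1.38, camera adjusted p = 2.07e-05, adjusted p = 0.143 with an estimated correlation). HSPE1 stood at -2.23 ± 0.0542. Of p53 targets 5 of 22 rose and 16 fell, median -0.52, camera adjusted p = 0.00666, adjusted p = 0.0553 with an estimated correlation. CDKN1A stood at -1.55 ± 0.0504 while BMF rose by 1.53 ± 0.0544. Ribosomal protein genes all rose (35 of 35 rose and 0 fell, median 0.58, camera adjusted p = 1.24e-10, adjusted p = 0.208 with an estimated correlation), and so did KIT (2.18 ± 0.108). Among the largest increases were SCARA5 (58.3-fold, 5.87 ± 0.193), the galectin gene LGALS2 (5.12 ± 0.127), TMEM86A (4.86 ± 0.141) and SIGLEC1 (4.66 ± 0.139). JPH2 and OCSTAMP had no read with the combination and 916 and 366 with DMSO, decreases of at least 283.4-fold and 112.5-fold. SPP1 fell 473.3-fold (95% counting interval 130.7 to 3914) and the chemokine gene CCL2 172-fold (58.55 to 836.5).

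limma called 11450 of 14421 genes changed against DMSO, 5672 higher and 5778 lower, 1804 and 1937 of them at least 2-fold, and groups lay apart in 79.3% of genes. Of the calls, 3522 rose and 3499 fell with MI-503 too (1691 and 1777 if independent; r = 0.753, 0.494 simulated). With AC220 4477 rose and 4584 fell alike (2136 and 2153 if independent; r = 0.856, 0.492 simulated), and part of these excesses may again come from the shared DMSO libraries. The ribosomal RNA precursor RNA45S5 took 4827 ± 663 RPM (mean ± SD) with the combination, 1645 ± 92.2 with DMSO, 2212 ± 46.3 with MI-503 and 2266 ± 73.2 with AC220. The 10 most abundant genes held 6.26% of reads with the combination and 4.63% with DMSO.

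Adding AC220 to MI-503 lowered DNA replication and mitosis genes. Against MI-503 alone (n = 3 per group), of DNA replication genes 0 of 26 rose and 26 fell, median -2.60, camera adjusted p = 1.16e-21. Of mitosis genes 0 of 25 rose and 25 fell, median -1.80, camera adjusted p = 2.64e-18, adjusted p = 0.110 with an estimated correlation. MYC and ribosome biogenesis genes all fell (0 of 28 rose and 28 fell, median -0.97, camera adjusted p = 1.78e-15). Of monocyte genes 15 of 22 rose and 3 fell, median 0.83, camera adjusted p = 0.00107. Of lysosome genes 22 of 27 rose and 4 fell, median 0.59, camera adjusted p = 7.63e-07. For cholesterol synthesis 0 of 24 rose and 22 fell, or 1 and 22 adjusted over the list alone, median -0.76, camera adjusted p = 2.70e-07, adjusted p = 0.166 with an estimated correlation. MHC class II genes rose (8 of 8 rose and 0 fell, median 1.15, camera adjusted p = 2.84e-04, adjusted p = 0.161 with an estimated correlation). Heat shock genes fell (1 of 11 rose and 10 fell, median -0.91, camera adjusted p = 2.84e-06, adjusted p = 0.145 with an estimated correlation), and histone genes rose (6 of 7 rose and 0 fell, median 1.51, camera adjusted p = 0.00158, adjusted p = 0.228 with an estimated correlation). RMRP and RPPH1, RNAs without poly(A) tails, were more abundant in these libraries as well. RMRP took 2.16 to 7.73 RPM with the combination and 1.03 to 1.76 with MI-503, and RPPH1 2.28 to 7.17 and 0.436 to 1.22. Each was highest in combination replicate 1, and RNA45S5 is given above. MLL fusion targets did not pass (9 higher and 8 lower of 20, camera adjusted p = 0.755). In all, limma called 9885 of 14421 genes changed, 5039 higher and 4846 lower, 822 and 1068 at least 2-fold.

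Adding MI-503 to AC220 lowered MLL targets and raised maturation genes. Against AC220 alone (n = 3 per group), of MLL fusion targets 1 of 20 rose and 18 fell, median -0.94, camera adjusted p = 1.91e-14. In the HOXA cluster 0 of 3 rose and 2 fell, median -1.37, camera adjusted p = 0.0240, adjusted p = 0.114 with an estimated correlation. Of monocyte genes 19 of 22 rose and 3 fell, median 1.20, camera adjusted p = 4.90e-08. Of granulocyte genes 6 of 11 rose and 1 fell, median 0.89, camera adjusted p = 0.0463, adjusted p = 0.274 with an estimated correlation. Of lysosome genes 24 of 27 rose and 2 fell, median 0.36, camera adjusted p = 7.69e-10. The class II list rose whole (8 of 8 rose and 0 fell, median 0.96, camera adjusted p = 2.62e-05, adjusted p = 0.115 with an estimated correlation). Of p53 targets 1 of 22 rose and 18 fell, median -0.28, camera adjusted p = 2.07e-05. MYC and ribosome biogenesis genes fell (1 of 28 rose and 24 fell, or 1 and 25 adjusted over the list alone, median -0.30, camera adjusted p = 4.90e-08, adjusted p = 0.114 with an estimated correlation), as did heat shock genes (1 of 11 rose and 8 fell, or 2 and 8 adjusted over the list alone, median -0.27, camera adjusted p = 0.0156, adjusted p = 0.387 with an estimated correlation). The mitosis list rose (25 of 25 rose and 0 fell, median 1.03, camera adjusted p = 1.17e-17, adjusted p = 0.114 with an estimated correlation). Cholesterol synthesis (10 higher and 4 lower of 24, or 12 and 4 adjusted over the list alone, camera adjusted p = 0.117), ATF4 (10 higher and 4 lower of 23, camera adjusted p = 0.222), DNA replication (13 higher and 7 lower of 26, camera adjusted p = 0.194) and ERK output (5 higher and 2 lower of 14, or 6 and 3 adjusted over the list alone, camera adjusted p = 0.502) did not pass. limma called 8007 of 14421 genes changed, 3954 higher and 4053 lower, 655 and 413 at least 2-fold.

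The interaction set the combination against the sum of the single-drug effects, a positive value meaning expression above that sum. BCL2 (-1.01 ± 0.0692, adjusted p = 4.29e-11, n = 3 per group) and CDK6 (-0.88 ± 0.0798, adjusted p = 5.16e-09) lay below the sum, so the drugs lowered these genes more together than their separate effects add up to. MYB (-0.42 ± 0.0548), SOCS2 (-0.55 ± 0.105) and FLT3 (-0.23 ± 0.0567) also lay below. MYC, which fell with each drug, did not pass (-0.15 ± 0.0593, adjusted p = 0.0507), though its call was gained under some alternative settings. PIM1 (2.01 ± 0.0791, adjusted p = 3.48e-15) lay above the sum, at -1.37 ± 0.0559 with the combination and -2.71 ± 0.0559 with AC220. DUSP6 (2.47 ± 0.194), EGR1 (3.07 ± 0.282), MEIS1 (0.31 ± 0.0814) and HOXA9 (0.51 ± 0.0843) lay above, MEF2C did not pass (0.05 ± 0.0813, adjusted p = 0.627), and LYZ lay below (-0.85 ± 0.0614).

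Several lists lay above the sum with the combination. Of cholesterol synthesis genes 23 of 24 lay above and 1 lay below, median 1.4, camera adjusted p = 7.02e-25. LSS stood at 2.94 ± 0.0948 and DHCR7 at 3.34 ± 0.298. In the ATF4 list 21 of 23 lay above and 1 lay below, or 22 and 1 adjusted over the list alone, median 1.15, camera adjusted p = 2.23e-17. TRIB3 stood at 3.95 ± 0.189. For ERK output 13 of 14 lay above and 0 lay below, median 2.0, camera adjusted p = 9.04e-07, adjusted p = 0.0619 with an estimated correlation. Only 4 members stayed at 100 or more under AC220 (median level 25.8). Others, perhaps DUSP6 and EGR1, may lie above the sum because they cannot fall further. For STAT5 targets 9 of 15 lay above and 2 lay below, or 10 and 2 adjusted over the list alone, median 0.55, camera adjusted p = 7.63e-04, adjusted p = 0.148 with an estimated correlation. Of glycolysis genes 19 of 21 lay above and 0 lay below, median 0.66, camera adjusted p = 4.74e-14, adjusted p = 0.0619 with an estimated correlation. ALDOC stood at 2.86 ± 0.201. Of mitosis genes 25 of 25 lay above and 0 lay below, median 1.11, camera adjusted p = 3.89e-21, adjusted p = 0.0934 with an estimated correlation. UBE2C, an enzyme of mitotic exit, stood at 1.53 ± 0.129 and MKI67 at 1.41 ± 0.0738. Of DNA replication genes 18 of 26 lay above and 1 lay below, median 0.44, camera adjusted p = 2.79e-05, adjusted p = 0.0619 with an estimated correlation. RRM2, a reductase that makes deoxynucleotides, stood at 1.47 ± 0.106 and CDC6 at 1.26 ± 0.137. The MHC class II list was below the sum (0 of 8 lay above and 6 lay below, median -0.74, camera adjusted p = 6.95e-04, adjusted p = 0.201 with an estimated correlation), HLA-DQB1 at -1.05 ± 0.0878. Ribosomal protein genes were below it as well (0 of 35 lay above and 25 lay below, or 0 and 30 adjusted over the list alone, median -0.17, camera adjusted p = 9.46e-06, adjusted p = 0.520 with an estimated correlation). MYC and ribosome biogenesis (5 higher and 7 lower of 28, or 5 and 8 adjusted over the list alone, camera adjusted p = 0.431), heat shock (5 higher and 2 lower of 11, or 6 and 2 adjusted over the list alone, camera adjusted p = 0.199) and MLL fusion targets (5 higher and 7 lower of 20, camera adjusted p = 0.392) did not pass.

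Large departures included the heme oxygenase gene HMOX1, 24.7-fold above the sum (4.63 ± 0.254), IFIT2 (4.33 ± 0.302), CD84, a lymphocyte and myeloid adhesion gene (-2.41 ± 0.0813), and F13A1 (-2.26 ± 0.0675). limma called 6133 of 14421 genes, 3014 above and 3119 below, 734 and 299 at least 2-fold.

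**Figure D2:**
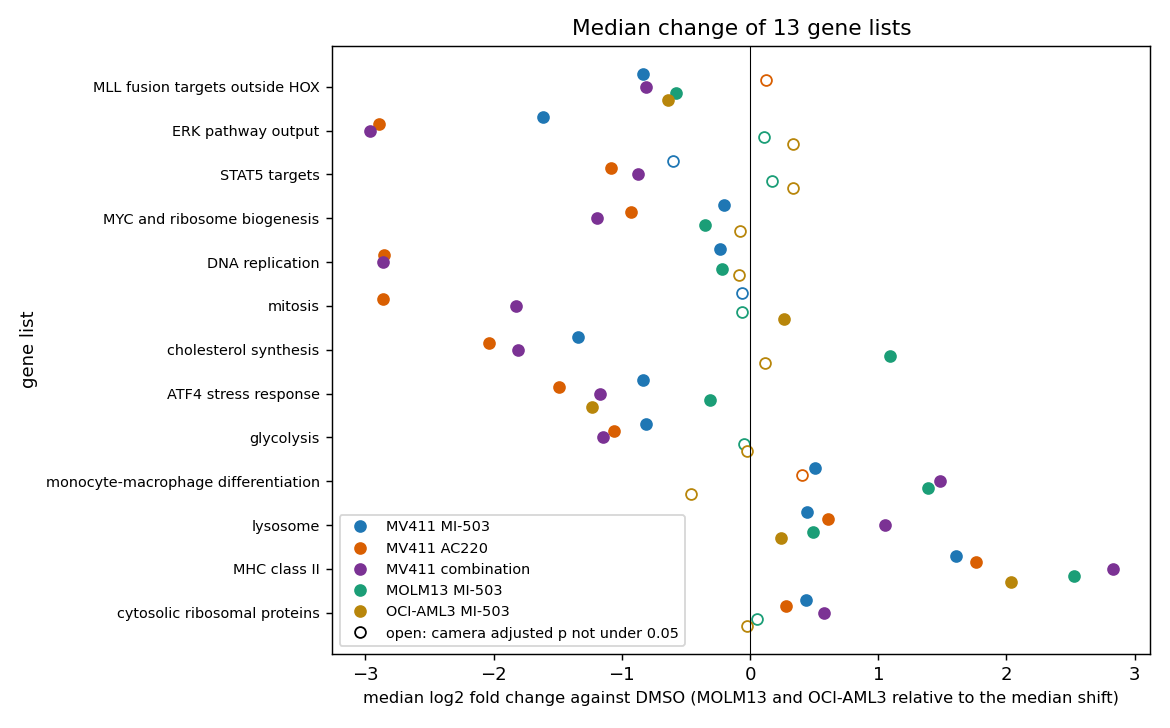
Median log2 fold change against DMSO (horizontal axis) of 13 gene lists (vertical axis) in 5 comparisons. MOLM13 and OCI-AML3 are relative to the median shift, and filled points had a camera adjusted p under 0.05.

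In MOLM13, MI-503 lowered MEIS1 to 0.319 of control relative to the median shift (-1.65 ± 0.0529, adjusted p = 1.49e-13, n = 3 per group), PBX3 to 0.155 (-2.69 ± 0.0431, adjusted p = 4.56e-17) and MEF2C to 0.195 (-2.36 ± 0.0359, adjusted p = 4.56e-17). ZNF521, a stem cell zinc finger gene of the MLL-fusion target list, changed by -2.12 ± 0.0403, CPEB2 by -1.90 ± 0.0569, FLT3 by -0.60 ± 0.0298 and CDK6 by -0.93 ± 0.0356. HOXA9 fell less than in MV411 (-0.33 ± 0.0415, adjusted p = 3.80e-06). HOXA10, which shares sequence of its gene model with HOXA9, was 0.09 ± 0.0356, adjusted p = 0.0459 relative to the shift but -0.45 ± 0.0952 on the deposited scale with adjusted p = 4.05e-06, so its direction rested on the scale. SOCS2 changed by -1.74 ± 0.0343 and MEN1 by -0.21 ± 0.0471, MYC by -0.18 ± 0.0278, and BCL2 did not pass (-0.08 ± 0.0360, adjusted p = 0.0799), though it did on the deposited scale (-0.61, adjusted p = 1.42e-10). PIM1 (0.57 ± 0.0533), MYB (0.38 ± 0.0266) and DUSP6 (0.36 ± 0.0454) rose relative to the shift, and on the deposited scale none passed, with adjusted p = 0.762, 0.0788 and 0.0809.

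Maturation genes rose in MOLM13: LYZ by 1.81 ± 0.0540, ITGAM, an integrin chain of mature myeloid cells, by 1.21 ± 0.0606, TLR4, the endotoxin receptor, by 2.58 ± 0.0847, CD36, a scavenger receptor, by 2.55 ± 0.0773, MNDA, a nuclear antigen of myeloid cells, by 2.53 ± 0.0471, and CSF1R, the receptor for the macrophage growth factor, by 2.43 ± 0.0903. CYBB rose by 2.76 ± 0.238, MPO by 1.32 ± 0.0650, KIT by 2.21 ± 0.197, and the immediate early genes EGR1 and FOS by 2.48 ± 0.295 and 2.13 ± 0.128. Large increases included SERPINB10 (70.5-fold, 6.14 ± 0.383), MARCKS, a membrane-bound kinase substrate (17.5-fold, 4.13 ± 0.0618), the chemokine receptor gene CCR2 (3.77 ± 0.0948), MS4A3 (3.55 ± 0.0726) and BPI, a granule antibacterial protein (3.52 ± 0.0808), and large decreases ALDH1A3 (-3.0 ± 0.0675) and EFNA5 (-2.48 ± 0.0995).

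Of monocyte genes 15 of 16 rose and 0 fell, median 1.39, camera adjusted p = 3.60e-10, adjusted p = 0.0856 with an estimated correlation. Of granulocyte genes 5 of 5 rose and 0 fell, median 1.47, camera adjusted p = 0.00103, adjusted p = 0.0856 with an estimated correlation. For the progenitor list 12 of 15 rose and 2 fell, median 0.35, camera adjusted p = 2.13e-04, adjusted p = 0.226 with an estimated correlation. MHC class II genes rose (4 of 4 rose and 0 fell, median 2.53, camera adjusted p = 0.00110, adjusted p = 0.0856 with an estimated correlation). HLA-DQB1 rose by 2.50 ± 0.172, CIITA by 2.69 ± 0.228 and CD74, the invariant chain, by 1.13 ± 0.0349. Of lysosome genes 22 of 26 rose and 1 fell, median 0.49, camera adjusted p = 3.34e-09, adjusted p = 0.0916 with an estimated correlation. ASAH1 rose by 1.19 ± 0.0322 and NPC2, a cholesterol carrier of the lysosome, by 1.35 ± 0.0609. Cholesterol synthesis genes rose (23 of 24 rose and 1 fell, median 1.09, camera adjusted p = 8.30e-15, adjusted p = 0.201 with an estimated correlation). HMGCS1 rose by 2.17 ± 0.0939, MSMO1, a sterol oxidase, by 1.79 ± 0.0466 and SQLE by 1.46 ± 0.0555. Of MLL fusion targets 3 of 23 rose and 16 fell, median -0.58, camera adjusted p = 3.34e-09, adjusted p = 0.0856 with an estimated correlation. In the HOXA cluster 2 of 11 rose and 9 fell, median -0.70, camera adjusted p = 0.0150, adjusted p = 0.201 with an estimated correlation. Of MYC and ribosome biogenesis genes 0 of 28 rose and 26 fell, median -0.35, camera adjusted p = 2.10e-11, adjusted p = 0.0856 with an estimated correlation. UTP20, a ribosome assembly gene, stood at -0.71 ± 0.0414. DNA replication (0 of 26 rose and 21 fell, median -0.22, camera adjusted p = 1.47e-06, adjusted p = 0.0856 with an estimated correlation) and heat shock genes (0 of 13 rose and 10 fell, median -0.36, camera adjusted p = 2.94e-06, adjusted p = 0.0856 with an estimated correlation) fell, HSPH1 at -0.70 ± 0.0277. In the ATF4 list 5 of 22 rose and 16 fell, median -0.32, camera adjusted p = 6.29e-05, adjusted p = 0.167 with an estimated correlation. DDIT4, a brake on growth signalling, stood at -1.25 ± 0.0303 and ASNS, the asparagine synthetase, at -0.71 ± 0.0390.

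ERK output (7 higher and 4 lower of 16, camera adjusted p = 0.436), STAT5 targets (6 higher and 4 lower of 14, or 6 and 5 adjusted over the list alone, camera adjusted p = 0.884) and ribosomal proteins (13 higher and 3 lower of 35, camera adjusted p = 0.0804) did not pass in MOLM13. On the deposited scale 3 ERK output genes rose and 10 fell, while camera placed the list above the other genes (camera adjusted p = 0.0493, adjusted p = 0.676 with an estimated correlation). There the lysosome list had 7 higher and 9 lower (6 and 9 adjusted over the list alone, median -0.05) and the progenitor list 5 and 8 (median -0.18), so their majority direction rested on the scale. On that scale limma called 11173 of 13393 genes, 903 higher and 10270 lower, with a median shift of -0.54. Relative to that shift the calls were 8020, 4083 higher and 3937 lower, 735 and 221 at least 2-fold (340 and 924 on the deposited scale). The deposited factor divided by the gene-based factor averaged 0.834 ± 0.0713 (mean ± SD) with DMSO and 1.203 ± 0.0534 with MI-503 (exact permutation p = 0.1, the smallest possible with 3 against 3), and the log2 difference in total value was -0.527 (exact permutation p = 0.1).

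**Figure D3:**
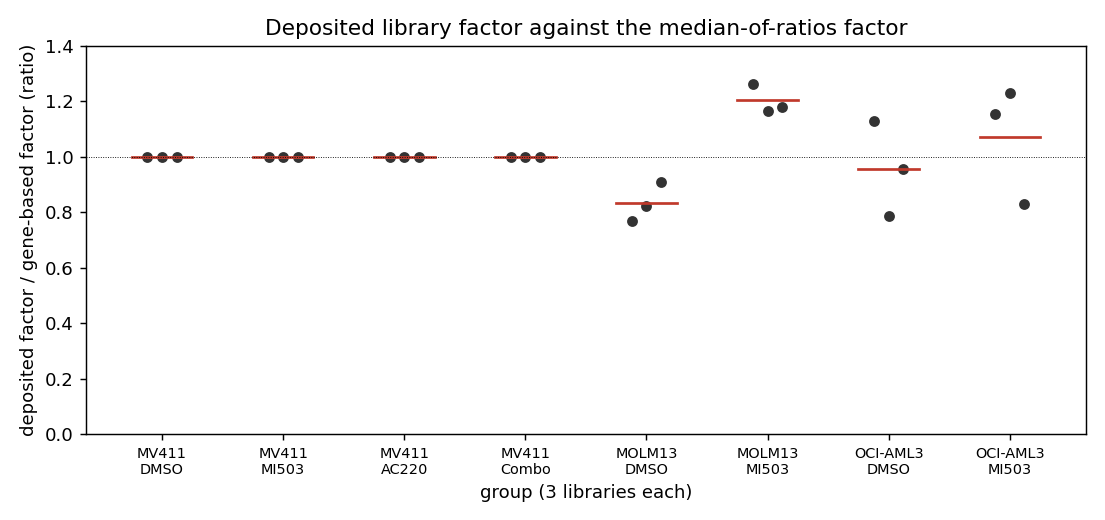
Deposited library factor divided by the median-of-ratios factor of the genes (vertical axis) for the 3 libraries of each of 8 groups (horizontal axis). Points are libraries, red bars are means, and 1 marks equality.

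OCI-AML3, without an MLL fusion, also lost MEIS1 with MI-503, to 0.163 of control relative to the median shift (-2.62 ± 0.0431, adjusted p = 3.17e-13, n = 3 per group). FLT3 fell to 0.478 (-1.07 ± 0.0339, adjusted p = 9.62e-11), PBX3 changed by -1.19 ± 0.0697, adjusted p = 2.13e-08 and BCL2 by -1.03 ± 0.0238, adjusted p = 6.51e-12. IGF2BP2, an RNA-binding protein gene, changed by -1.57 ± 0.0288, RUNX2, a transcription factor gene, by -1.32 ± 0.0364 and CDK6 by -0.63 ± 0.0261. HOXB3, a homeobox gene often high with mutant NPM1, changed by -0.96 ± 0.0466 and HOXA13 by -0.67 ± 0.0283. HOXA9 (-0.34 ± 0.0295, adjusted p = 7.34e-07) and HOXA10 (-0.48 ± 0.0266, adjusted p = 1.41e-08) fell relative to the shift but did not pass on the deposited scale, and the calls of MEF2C (-0.26 ± 0.0358), MYB (-0.24 ± 0.0286), KMT2A (-0.25 ± 0.0370), NPM1 (-0.14 ± 0.0228) and LYZ (0.66 ± 0.0238) were lost there too. MYC moved up slightly (0.11 ± 0.0396, adjusted p = 0.0305), also only relative to the shift, and MEN1 did not pass (-2.26e-04 ± 0.0434, adjusted p = 0.997).

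Maturation markers split in OCI-AML3. ITGAM rose by 2.42 ± 0.0707 and PRTN3, a granule protease gene, by 1.14 ± 0.0373, while CD14, the endotoxin co-receptor, changed by -0.68 ± 0.0641, CSF1R by -2.46 ± 0.110, VCAN, a matrix proteoglycan of monocytes, by -2.01 ± 0.0408, CYBB by -1.74 ± 0.0240, FPR1, the formyl peptide receptor, by -3.32 ± 0.135 and S100P, a calcium-binding protein gene, by -4.44 ± 0.304. CISH and STAT5A rose by 1.05 ± 0.0649 and 1.53 ± 0.112. Large increases included CDH6, a cadherin (30.8-fold, 4.94 ± 0.0992), CXCL11, an interferon-induced chemokine (19.5-fold, 4.29 ± 0.0925), and SERPINB10 (3.39 ± 0.0457). The largest decreases included LSP1, a leukocyte cytoskeleton gene (-4.77 ± 0.129), the hormone genes STC2 and ADM2 (-4.06 ± 0.0531 and -3.88 ± 0.0642) and SULF2, an extracellular sulfatase (-3.84 ± 0.0743).

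The ATF4 list fell almost whole (0 of 23 rose and 22 fell, median -1.23, camera adjusted p = 3.24e-15, adjusted p = 0.145 with an estimated correlation). CHAC1, which degrades glutathione, stood at -4.31 ± 0.106, PHGDH at -3.46 ± 0.0572 and SLC7A11, the cystine transporter, at -2.99 ± 0.0397. Of MLL fusion targets 2 of 20 rose and 17 fell, median -0.64, camera adjusted p = 4.39e-07, adjusted p = 0.332 with an estimated correlation. In the HOXA cluster 0 of 11 rose and 7 fell, median -0.42, camera adjusted p = 0.0346, adjusted p = 0.332 with an estimated correlation. Oxidative phosphorylation genes rose (27 of 30 rose and 2 fell, median 0.30, camera adjusted p = 4.10e-07, adjusted p = 0.0880 with an estimated correlation). NDUFA8, a complex I subunit, rose by 1.01 ± 0.0343. Mitosis genes rose (18 of 25 rose and 0 fell, or 19 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 3.79e-05, adjusted p = 0.318 with an estimated correlation). CENPE, a spindle motor, rose by 1.04 ± 0.0384. Of lysosome genes 16 of 27 rose and 7 fell, median 0.25, camera adjusted p = 0.0127, adjusted p = 0.270 with an estimated correlation. NPC2 rose by 1.51 ± 0.0356 and the protease gene CTSL by 1.05 ± 0.0333. Class II genes rose (3 of 3 rose and 0 fell, median 2.03, camera adjusted p = 0.0456, adjusted p = 0.332 with an estimated correlation). CIITA rose by 2.10 ± 0.160. For p53 targets 13 of 22 rose and 4 fell, median 0.25, camera adjusted p = 0.0456, adjusted p = 0.318 with an estimated correlation. For interferon response 4 of 28 rose and 18 fell, or 4 and 19 adjusted over the list alone, median -0.48, camera adjusted p = 0.0114, adjusted p = 0.382 with an estimated correlation. Of granulocyte genes 2 of 9 rose and 6 fell, median -1.01, camera adjusted p = 0.0456, adjusted p = 0.318 with an estimated correlation. For histone genes 0 of 13 rose and 11 fell, median -0.29, camera adjusted p = 0.00515, adjusted p = 0.382 with an estimated correlation. The camera calls of the HOXA, mitosis, lysosome, p53 and histone lists were lost on the deposited scale, where only 1 oxidative phosphorylation gene passed higher and 0 lower (0 and 0 adjusted over the list alone). Monocyte genes (9 higher and 13 lower of 25, or 9 and 14 adjusted over the list alone, camera adjusted p = 0.168), cholesterol synthesis (12 higher and 4 lower of 24, camera adjusted p = 0.105), ERK output (10 higher and 5 lower of 18, camera adjusted p = 0.168, EPHA2, a receptor kinase, at 2.27 ± 0.103 and PHLDA1 at -1.0 ± 0.0466) and STAT5 targets (8 higher and 3 lower of 14, camera adjusted p = 0.165) did not pass. On the deposited scale the monocyte list passed as lower (2 higher and 11 lower, or 2 and 12 adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.915 with an estimated correlation).

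On the deposited scale limma called 1676 of 15700 genes, 605 higher and 1071 lower, with a median shift of -0.16 (exact permutation p = 0.4 for totals), and 10291 relative to that shift, 5161 higher and 5130 lower, 594 and 513 at least 2-fold (409 and 675 on the deposited scale). The smaller first count went with uneven deposited factors: divided by the gene-based factor they were 1.13, 0.785 and 0.957 with DMSO and 1.16, 1.23 and 0.831 with MI-503. The OCI-AML3 libraries held far more RNA without poly(A) tails than those of the other lines, although the labels name polyA RNA for every sample. RNase P and MRP RNA took 20263 to 21773 RPM there, 1.06 to 14.9 in MV411 and 0.579 to 1.33 in MOLM13, and 73 histone genes took 7632 to 9838, 43.2 to 149.4 and 13.9 to 15.7. RNA45S5 took 7849 ± 972 RPM (mean ± SD) with DMSO and 10385 ± 1083 with MI-503.

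Between MV411 and MOLM13 the sterol pathway separated the MI-503 effects of the 2 MLL-fusion lines, which were treated for 3 and 4 days. HMGCS1 differed by -4.40 ± 0.131, adjusted p = 1.25e-17 (MV411 minus MOLM13, n = 3 per group), LSS by -3.82 ± 0.0858, adjusted p = 3.23e-19. In that list 0 of 24 lay higher and 23 lay lower, median -2.34, camera adjusted p = 1.24e-22, adjusted p = 0.0895 with an estimated correlation. MEIS1 fell in each line, PBX3 fell less in MV411 (difference 0.90 ± 0.0637), and HOXA9 (-1.54 ± 0.0731) and HOXA10 (-1.61 ± 0.0633) fell more in MV411. DUSP6 (-2.72 ± 0.0952) and EGR1 (-5.26 ± 0.385) led the ERK list, where 0 of 12 lay higher and 12 lay lower, median -1.99, camera adjusted p = 1.29e-07. BCL2 (-0.99 ± 0.0526) and PIM1 (-1.23 ± 0.0702) were lower and SOCS2 (1.62 ± 0.0688) higher in MV411. MYC (-0.69 ± 0.0489) and MYB (-0.71 ± 0.0459) were lower too, without passing on the deposited scale (adjusted p = 0.0968 and 0.0650).

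In the ATF4 list 1 of 22 lay higher and 16 lay lower, median -0.57, camera adjusted p = 4.43e-08. TRIB3 stood at -2.46 ± 0.0670 and ATF5 at -1.80 ± 0.0678. Of glycolysis genes 3 of 21 lay higher and 17 lay lower, median -0.60, camera adjusted p = 2.02e-07, adjusted p = 0.0744 with an estimated correlation. ALDOC stood at -5.29 ± 0.183. Of ribosomal protein genes 35 of 35 lay higher and 0 lay lower, median 0.39, camera adjusted p = 1.12e-14, adjusted p = 0.244 with an estimated correlation. RPS16 stood at 0.58 ± 0.0492. Of monocyte genes 4 of 16 lay higher and 9 lay lower, median -1.04, camera adjusted p = 0.0214, adjusted p = 0.364 with an estimated correlation. CSF1R stood at -2.12 ± 0.106, IFIT2 was lower (-4.18 ± 0.298) and ELANE was higher in MV411 (1.82 ± 0.0883). In the HOXA cluster 0 of 3 lay higher and 2 lay lower, median -1.54, camera adjusted p = 0.0344, adjusted p = 0.177 with an estimated correlation. Of MLL fusion targets 5 of 20 lay higher and 12 lay lower, or 5 and 14 adjusted over the list alone, median -0.41, camera adjusted p = 0.0490, adjusted p = 0.518 with an estimated correlation. limma called 9927 of 12736 genes on the deposited scale, 8900 higher and 1027 lower with a median shift of 0.52, and 7303 relative to it, 3424 higher and 3879 lower, 235 and 813 at least 2-fold (1440 and 415 on the deposited scale).

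**Figure D4:**
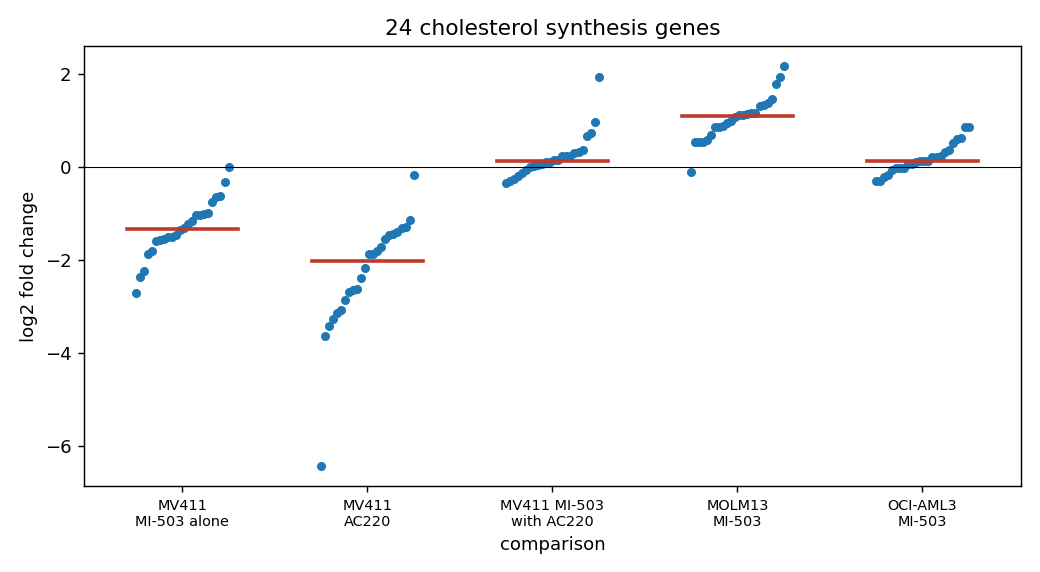
Log2 fold changes (vertical axis) of 24 cholesterol synthesis genes in 5 comparisons (horizontal axis), red bars marking medians. MOLM13 and OCI-AML3 are relative to the median shift, and the third column sets the combination against AC220.

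Between MV411 and OCI-AML3 (MV411 minus OCI-AML3, n = 3 per group) the HOXA genes separated the lines: HOXA9 differed by -1.53 ± 0.0653, adjusted p = 2.49e-13 and HOXA10 by -1.05 ± 0.0547, adjusted p = 5.10e-12. In the cluster 0 of 3 lay higher and 2 lay lower, median -1.05, camera adjusted p = 0.0202, adjusted p = 0.125 with an estimated correlation. MEF2C (-2.54 ± 0.0725) and MYC (-0.98 ± 0.0581) were lower in MV411. CYBB (4.29 ± 0.0762), S100A8 (3.56 ± 0.0949) and LYZ (1.91 ± 0.0499) were higher and ITGAM lower (-2.59 ± 0.0984). Of monocyte genes 15 of 20 lay higher and 3 lay lower, median 1.57, camera adjusted p = 4.04e-05, adjusted p = 0.0675 with an estimated correlation. Of granulocyte genes 7 of 9 lay higher and 1 lay lower, median 1.53, camera adjusted p = 0.00566, adjusted p = 0.143 with an estimated correlation. Of cholesterol synthesis genes 0 of 24 lay higher and 23 lay lower, median -1.53, camera adjusted p = 2.56e-15, adjusted p = 0.0774 with an estimated correlation. DHCR7 stood at -2.68 ± 0.0740 and HMGCS1 at -2.60 ± 0.0816. Of ERK output genes 0 of 13 lay higher and 13 lay lower, median -1.62, camera adjusted p = 1.11e-07, adjusted p = 0.0675 with an estimated correlation. DUSP6 stood at -2.01 ± 0.107 and EGR1 at -3.48 ± 0.155. For the ATF4 list 17 of 23 lay higher and 3 lay lower, median 0.47, camera adjusted p = 9.95e-05, adjusted p = 0.0960 with an estimated correlation. CHAC1 stood at 2.41 ± 0.166. Of glycolysis genes 3 of 21 lay higher and 17 lay lower, median -0.64, camera adjusted p = 3.94e-06, adjusted p = 0.201 with an estimated correlation. ALDOC stood at -3.97 ± 0.168.

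Ribosomal protein genes were all higher in MV411 (35 of 35 lay higher and 0 lay lower, median 0.46, camera adjusted p = 9.29e-13, adjusted p = 0.143 with an estimated correlation). RPS16 stood at 0.75 ± 0.0546. Of STAT5 targets 1 of 14 lay higher and 12 lay lower, median -0.77, camera adjusted p = 9.54e-04, adjusted p = 0.201 with an estimated correlation. Of p53 targets 5 of 21 lay higher and 12 lay lower, median -0.49, camera adjusted p = 0.00314, adjusted p = 0.0697 with an estimated correlation. CDKN1A stood at -1.62 ± 0.0582. MLL fusion targets did not differ as a list (7 higher and 7 lower of 20, camera adjusted p = 0.496). limma called 2629 of 13447 genes on the deposited scale, 1731 higher and 898 lower with a median shift of 0.16, and 8577 relative to it, 4333 higher and 4244 lower, 607 and 741 at least 2-fold (847 and 571 on the deposited scale). The line difference was confounded with days of treatment and with the library content of OCI-AML3 given above.

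Between MOLM13 and OCI-AML3, each treated for 4 days (MOLM13 minus OCI-AML3, n = 3 per group), monocyte genes separated the lines. CSF1R differed by 4.89 ± 0.166, adjusted p = 7.55e-14, CYBB by 4.50 ± 0.25, adjusted p = 5.91e-11 and S100P by 5.91 ± 0.390, adjusted p = 5.98e-10, while ITGAM rose more in OCI-AML3 (-1.20 ± 0.10). Of monocyte genes 11 of 16 lay higher and 2 lay lower, median 1.62, camera adjusted p = 3.62e-05, adjusted p = 0.0821 with an estimated correlation. Of granulocyte genes 4 of 5 lay higher and 0 lay lower, or 5 and 0 adjusted over the list alone, median 1.28, camera adjusted p = 0.00478, adjusted p = 0.0623 with an estimated correlation. MEF2C (-2.09 ± 0.0549), PBX3 (-1.5 ± 0.0864) and SOCS2 (-1.79 ± 0.0818) were lower in MOLM13. BCL2 (0.96 ± 0.0441) and MEIS1 (0.97 ± 0.0696) fell more in OCI-AML3, without passing on the deposited scale (adjusted p = 0.0906 and 0.0913). Of ATF4 genes 20 of 22 lay higher and 0 lay lower, median 0.99, camera adjusted p = 1.95e-12, adjusted p = 0.0623 with an estimated correlation. CHAC1 stood at 3.39 ± 0.209 and SLC7A11 at 3.35 ± 0.113. Of cholesterol synthesis genes 22 of 24 lay higher and 1 lay lower, median 0.87, camera adjusted p = 2.45e-09, adjusted p = 0.232 with an estimated correlation. HMGCS1 stood at 1.80 ± 0.132 and SQLE at 1.49 ± 0.0765. Of oxidative phosphorylation genes 0 of 30 lay higher and 27 lay lower, or 0 and 28 adjusted over the list alone, median -0.37, camera adjusted p = 4.28e-10, adjusted p = 0.0623 with an estimated correlation. NDUFA8 stood at -1.08 ± 0.0549.

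Of MYC and ribosome biogenesis genes 2 of 28 lay higher and 21 lay lower, median -0.27, camera adjusted p = 4.09e-05, adjusted p = 0.0623 with an estimated correlation. Of heat shock genes 0 of 12 lay higher and 9 lay lower, median -0.51, camera adjusted p = 5.82e-05, adjusted p = 0.0623 with an estimated correlation. MLL fusion targets did not differ as a list (9 higher and 8 lower of 20, camera adjusted p = 0.776), their median and test pointing up and their mean down. Among the other large differences were LSP1 (5.78 ± 0.182) and CXCL11 (-4.95 ± 0.195). limma called 3222 of 13030 genes on the deposited scale, 612 higher and 2610 lower with a median shift of -0.37, and 8185 relative to it, 4249 higher and 3936 lower, 804 and 369 at least 2-fold (416 and 984 on the deposited scale). MI-503 effects correlated weakly between lines: r = 0.261 for MV411 and MOLM13, 0.237 for MV411 and OCI-AML3, and 0.193 for MOLM13 and OCI-AML3.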

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

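The tests of explanations in this part were chosen after the results were seen, whereas the tests of differences between lines were planned. These results were picked out because the MI-503 effect differed between 2 lines relative to the median shift. MOLM13 and OCI-AML3 differed at 8185 genes, among them S100P (5.91) and CXCL11 (-4.95). MV411 and OCI-AML3 differed at 8577, among them CYBB (4.29) and ALDOC (-3.97). MV411 and MOLM13 differed at 7303, among them ELANE (1.82) and ALDOC (-5.29), and by the medians of ERK output (-1.99) and the ATF4 list (-0.57).

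Cholesterol synthesis genes fell with MI-503 in MV411 and rose in MOLM13. Table scale can be excluded, since the median difference stayed at -2.34 on the median-ratio scale. That 23 of 24 members were lower restates the pattern and excludes nothing. Treatment length, 3 against 4 days, stayed open, as 0 lines had both. A line difference in sterol feedback was not tested.

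RNAs without a poly(A) tail took a far larger share of reads in OCI-AML3. Libraries without poly(A) selection would raise all such RNAs, but 4 of 4 raised classes only restate the pattern. The labels name polyA RNA throughout. Deeper sequencing can be excluded, as the lowest OCI-AML3 histone share was 51.08 times the highest elsewhere, and median depths differed 2.39-fold. Lack of poly(A) selection stayed open, as 0 tables held more than 1 line. RNase P and MRP RNA (at least 20263 RPM, at most 14.9 elsewhere) argue against line expression alone.

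Most MOLM13 genes were lower with MI-503 on the deposited scale. Sequencing depth can be excluded, with a log2 difference in reads of only -0.069, and so can a change in the most abundant genes, whose share moved by -0.182 points. A difference in spike-in or counted cells stayed open. The exact permutation p = 0.1, the smallest that 3 against 3 libraries allow, asks only whether the factor ratios differ between the groups. It cannot say why they differ. Less RNA per cell could give the same values and was not tested.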

How the results depend on the processing

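Alternatives for the planned counts were fixed in advance, and those for counts relative to the median shift were chosen after the data were seen. With an added limit of 1 on the absolute log2 fold change, the calls were 1241 for MI-503 in MV411, 2786 for AC220, 3741 for the combination, 1890 against MI-503, 1068 against AC220, 1033 for the interaction, 1264 in MOLM13, 1084 in OCI-AML3, 1400 for MOLM13 against OCI-AML3, 1418 for MV411 against OCI-AML3 and 1855 for MV411 against MOLM13. With an estimated correlation camera called 3, 2, 5, 4, 4, 2, 0, 0, 0, 0 and 2 lists in the same order, the last 5 relative to the median shift. On the deposited scale MOLM13 against OCI-AML3 kept granulocyte differentiation (adjusted p = 0.00956). The OCI-AML3 count of 1676 became 10291 with median-ratio scaling, 10331 with equal totals and 10352 with TMM, and ran from 711 without DMSO replicate 3 to 3338 without MI-503 replicate 3. The MOLM13 and OCI-AML3 difference of 3222 became 8185, 8353 and 8274 on these scales, and ran from 1794 without MOLM13 DMSO replicate 1 to 5334 without OCI-AML3 DMSO replicate 2. The MV411 and OCI-AML3 difference of 2629 became 8577, 8645 and 8670, and ran from 1758 without MV411 DMSO replicate 1 to 5449 without OCI-AML3 MI-503 replicate 3. The median shift ran from -0.02 without DMSO replicate 2 (640 higher, 505 lower) to -0.34 without MI-503 replicate 3 in OCI-AML3, and without the same libraries from 0.02 (1207 higher, 1252 lower) to 0.33 for MV411 against OCI-AML3 and from -0.50 to -0.20 for MOLM13 against OCI-AML3. The cause was not tested. Without genes of non-polyadenylated RNA the counts relative to the shift were 10176 in OCI-AML3, 8142 for its difference from MOLM13 and 8522 for that from MV411. A minimum value of 50 moved the median log2 fold change to -0.0035 for AC220, -0.012 for the combination and 0.0087 for the combination against MI-503. HOXA10 in MOLM13 turned to -0.45 on the deposited scale. Of 292 gene values checked, 267 kept their call or its absence under every alternative.

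A replicate block gave 1012 calls in OCI-AML3, 1818 for MOLM13 against OCI-AML3 and 1758 for MV411 against OCI-AML3, and ended the camera calls of DNA replication (MV411 against OCI-AML3, adjusted p = 0.0574) and MLL fusion targets (MV411 against MOLM13, adjusted p = 0.0518). Replicate numbers did not pair libraries: residuals of libraries with the same number correlated at r = -0.081 to 0.121 in MV411, and 5 of 18 pairs there matched best with their own number.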

Other observations

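The line overlaps, the hypotheses and the regroupings in this part were chosen after the results were seen. MI-503 changed a small shared set in all 3 lines relative to the median shift. Of 12634 genes tested in each, 915 rose and 890 fell in every line, against 400.1 and 420.2 for independent calls, and 43 rose and 9 fell at least 2-fold, against 0.383 and 0.0888. The 9 that fell include MEIS1 and PBX3. The 43 that rose include MARCKS, SERPINB10, CIITA and HLA-DQB1, picked after their values were seen. At least 2-fold, 144 genes rose and 44 fell in both MV411 and MOLM13, against 18.2 and 4.91 if independent, while 3 and 72 went opposite ways, against 26.5 together.

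OCI-AML3 and MV411 shared 95 increases and 104 decreases of at least 2-fold (13.3 and 14.1 if independent), and MOLM13 and OCI-AML3 shared 112 and 24 (17.4 and 3.96). Opposite changes of that size exceeded independence too, at 20 and 37 against 27.6 together for MV411 and OCI-AML3 and 47 and 8 against 19.2 together for MOLM13 and OCI-AML3. Over calls of any size they were fewer than if independent: 543 and 978 against 2396 for MV411 and MOLM13, 1086 and 1148 against 2844 for MV411 and OCI-AML3, and 1236 and 1068 against 2709 for MOLM13 and OCI-AML3. By camera with the preset correlation the ATF4 amino-acid list fell in all 3 lines, a call lost in MOLM13 (adjusted p = 0.167) and OCI-AML3 (adjusted p = 0.145) with an estimated correlation. Relative to the median shift the cholesterol synthesis and ERK output lists fell only in MV411, calls also lost with an estimated correlation (adjusted p = 0.0580 and 0.0674).

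One hypothesis is that MI-503 lowers cholesterol synthesis genes in MV411 through loss of a signal that AC220 also blocks. It predicts little further change when MI-503 is added to AC220, and the list median was then 0.12, against -1.34 with MI-503 alone, with 22 of 24 members still at 100 or more under AC220. The value of 0.12 is consistent with that hypothesis, and a shared fall in growth rate could give the same result. An MI-503 series with FLT3 activity restored would test it. For ERK output the same value was 0.20, with 2 of 14 members lower, but its low levels under AC220 left this undecided.

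Libraries were regrouped to count calls under other groupings. Mixed groups hold drug effects in their spread, which lowers their counts, so a real count on top decides nothing, the interaction included. With 3 against 3 only 10 splits exist, too few for a share under 0.05. The 5 MV411 pairwise comparisons and MOLM13 (11173) had 0 as the highest other count, so 1 split of 10 was as large in each. In OCI-AML3 2 of 10 splits reached 1676, and the highest other, 7092, set DMSO 1, MI-503 1 and MI-503 2, the libraries with the highest ratio of deposited to gene-based factor, against the rest. Relative to the shift OCI-AML3 gave 10291 with 0 as the highest other, so 7092 followed the deposited factors.

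For the interaction 1 of 100 drawn regroupings, the real one, reached 6133 (highest other 4176). For MV411 against MOLM13 1 of 100 reached 9927 (highest other 7813), and 1 of 100 reached 7303 relative to the shift (4417). The regrouping that exchanges treatments in 1 line was not among those drawn there and gave 9837, and 8698 relative to the shift, more than 7303. MV411 against OCI-AML3 had 2 of 100 at 2629 (highest other 6883, and 3811 for the exchange, not drawn) and 2 at 8577 relative to the shift (9372). MOLM13 against OCI-AML3 had 4 of 100 at 3222 (8076) and 2 at 8185 relative to the shift (8741). The values 9372, 8741 and 8076 belong to that same exchange, which measures the sum of the effects.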
